A study of Drosophila melanogaster with 3 samples.

How the data were processed

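The series holds chromatin immunoprecipitation followed by sequencing (ChIP-seq) of the forkhead transcription factor Jumeau (jumu) in whole Drosophila melanogaster embryos aged 0 to 24 hours, sexes mixed. Per the labels, the flies carried an eGFP exon inserted in an intron of jumu, so that the protein was made as a fusion with eGFP, and the precipitation used an antibody against GFP. Chromatin was sheared by sonication to fragments of 200 to 800 bp, per the labels. There was 1 group of 3 biological replicates, numbered by the labels, and no control sample was analysed here. The deposited readme files name a shared control alignment, which was not used here.

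The authors deposited peak lists in 2 genome builds, dm6 and dm3. Per the deposited readme files, each replicate had a relaxed list of peaks and background made as input for the irreproducible discovery rate procedure, the pooled replicates had another, and the optimal list was thresholded by that procedure. The peak caller, its settings, the threshold and the sequencing depth are not given in the sources used here, so the depth behind each peak is unknown. The signal of each peak is the authors' own value from their peak caller, and it was used only to rank, describe or filter peaks within a list, or as a value relative to the median of its replicate. The lists also carry a −log10 q value per peak, as deposited, which was not used for selection. The readme files hold no measurement, and the dm3 lists were used for counts and as an alternative in the comparison of replicates. Each dm6 replicate list held exactly 30000 peaks and the pooled list 29812. The 3845 optimal peaks of dm6 were all entries of the pooled list, and exactly 3845 pooled peaks had a signal at or above that of the weakest optimal peak, 112.0. Thus a peak outside the optimal list is a weaker pooled peak, and its absence does not show that the protein was absent. In 1 optimal peak the summit lay outside the interval, and the peak was kept.

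Coordinates are 1-based, in dm6. Gene models came from the Ensembl annotation of BDGP6.54, the same assembly, without transposable elements, which left 18164 genes and 23581 transcription start site (TSS) positions on the 6 arms 2L, 2R, 3L, 3R, 4 and X. A summit was called promoter within 500 bp of any annotated TSS, and otherwise took the first of 5' UTR, coding sequence (CDS), 3' UTR, other exon, intron and intergenic that applied. A protein-coding gene was called bound when an optimal summit lay within 1 kb of any of its TSSs. That is an assignment by position, the summit can lie nearer to another gene, and with no control sample analysed here, signal of the antibody or of open promoters was not separated from binding.

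Replicate peaks were matched to optimal peaks by summits within 100 bp, taking the strongest. The rank agreement was Spearman's rho of signal across optimal peaks matched in all 3 replicates, with a standard error from 1000 bootstrap draws of 1 Mb blocks. It is a correlation across peaks, which are not independent replicates, so no p is given. To set replicates side by side, a replicate's signal at a peak was divided by that replicate's median over its matched optimal peaks. This relative signal is given as mean ± SD over the 3 replicates. Shares carry 95% Wilson intervals, which treat peaks or genes as independent. Where no member of a list was bound, the share said to be allowed is 3 divided by the number of members. It is an approximate limit, coarse for short lists, and differs from the Wilson interval drawn in the figure.

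Location was compared with 1000 random placements of the summits within their arm (two-sided empirical p) and, by Fisher's exact test, with the 25199 relaxed pooled peaks that overlapped no optimal peak, both adjusted over 7 classes. Arms were tested by a two-sided exact binomial test against arm length, adjusted over 6 arms. Gene lists were tested by two-sided Fisher's exact tests against all other protein-coding genes, adjusted over 31 lists. Of the listed symbols, 8 had no match in the annotation and are not analysed here. Consensus words were sought on both strands in 101 bp around the summit and in an equal window centred 500 bp to one randomly drawn side, and were compared by a two-sided exact McNemar test, adjusted over 14 words. Promoter and other peaks were compared by a two-sided permutation test of the difference in median signal with 100000 resamples. All adjustments are Benjamini-Hochberg, with a threshold of 0.05. An adjusted exact p is an adjusted p from one of these exact tests.

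The tests, lists, words and alternatives were fixed before the data were examined, except where the closing section says otherwise and except for the tests of words by location, of the side of the start site, of the X within replicates and of genes that make no protein, which were added later. The lists of ribosomal, proteasome, heat shock, receptor, seminal fluid, cuticle, chorion and protease genes were drawn by symbol. In these, 2 members of the seminal fluid and 2 of the chorion list are of another kind, and both lists are also given without them. Named genes were chosen by a rule fixed then too. It took the nearest-TSS gene of the 20 strongest optimal peaks, up to 3 bound members with the strongest peak in each list past the threshold, all 16 candidate genes linked to jumu, and the 5 protein-coding genes with the most optimal peaks in the gene or within 1 kb of it. Other list members, and genes nearer to a named peak, are named as examples chosen after their values were seen. Alternatives covered the matching distance, each replicate left out in turn, stricter peak sets, other TSS windows, other backgrounds and other control windows. Outside the comparison of replicates, leaving out replicate 1, 2 or 3 also gave a smaller peak set, with 2411, 2612 and 2655 peaks. The optimal list held 3845. A call lost or gained there can come from the smaller set and is not put down to the replicate left out.

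The functions were tested on simulated data with known answers. In 100 draws over 13945 genes, a planted gene list was called in 100% and null lists in 0.133%. With 3845 random peaks, any arm was called in 6% of 100 null draws, and a chromosome 4 deficit made by thinning was found in 96%. A word planted in random summits was called in 100% of 10 draws and the other words in 0%. Random summits were placed without regard to base composition, while optimal summits had 37.8% GC against 43.9% at 500 bp. The 0% therefore does not cover calls that follow composition. Permutation tests on 300 simulated values called 3% of 100 null draws. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.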

Results

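Binding of Jumeau was assayed in 3 biological replicates of whole embryos from flies whose jumu gene makes an eGFP fusion protein. Jumeau is a forkhead transcription factor known from heart, muscle and nervous system development and as a modifier of position-effect variegation. The optimal list held 3845 peaks with a median signal of 180.6 and a median width of 420 bp. The median signal of the matched peaks was 74.8 in replicate 1, 58.1 in replicate 2 and 54.5 in replicate 3. Sequencing depth is unknown, so these medians are not comparable between replicates, and the intervals given cover counting error only. No control sample was analysed here, so signal from the antibody or from open promoters was not separated from binding of Jumeau, and a gene called bound is one with a peak within 1 kb of a start site. With 1 group, the comparisons were between replicates, between optimal peaks and genomic backgrounds, and between groups of genes.

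The first comparison asked how far the replicates shared their peaks. Optimal peaks were found again in each replicate, and the strongest, at cbt, Ugalt and CG14100, stood far above the median in all 3. Of the 3845 optimal peaks, 97.9% (95% interval 97.4 to 98.3%) had a summit of replicate 1 within 100 bp. The share was 94.3% (93.6 to 95%) in replicate 2 and 95.4% (94.7 to 96.1%) in replicate 3, and 3411 peaks (88.7%, 87.7 to 89.7%) were matched in all 3. Summits placed at random were matched in only 4.50 to 4.65% of cases. The order of peak signals was shared less closely. Spearman's rho across the 3411 peaks was 0.79 ± 0.0081 (bootstrap SE) for replicates 1 and 2, 0.75 ± 0.0088 for 1 and 3, and 0.70 ± 0.0092 for 2 and 3. Without the choice of optimal peaks, the 3845 strongest peaks of a pair of replicates overlapped by 67.2% ± 3.56 (SD, n = 3 pairs). The optimal list was itself chosen for agreement between replicates.

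The next comparison asked where in the genome the peaks lay. Most summits lay at promoters, few in intergenic DNA and almost none in coding sequence. Promoters held 2211 summits, or 57.5% (55.9 to 59.1%), against 13.5% ± 0.564 (SD over random placements), a ratio of 4.24. Introns held 1105 summits (28.7%), fewer than the 39.5% of random placements, and intergenic DNA 438 (11.4%), fewer than 27.1%. Coding sequence held 19 summits, or 0.494% (0.317 to 0.771%), against 13.8% at random. These 4 classes and the 3' UTR differed from random placement (n = 3845 summits, adjusted p = 0.0014 each, from the smallest p that 1000 placements can give), while the 5' UTR (adjusted p = 0.143) and other exons (adjusted p = 0.414) did not pass. The weaker relaxed peaks were placed differently, with 24.5% at promoters and 27.3% in coding sequence. The odds of a promoter summit were 4.18 times higher among optimal peaks than among these relaxed peaks by Fisher's exact test. Against them introns did not pass (29.5% of relaxed summits, odds ratio 0.962, adjusted exact p = 0.323), while the 5' UTR passed as lower (odds ratio 0.441, adjusted p = 0.000111).

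Promoter summits sat close to the start site, at a median of 93 bp, and 1741 of the 2211 (78.7%, 77.0 to 80.4%) lay upstream of it (two-sided exact binomial p = 8.83e-171). The nearest start site belonged to a protein-coding gene in 94.1% of them. Only 172 optimal summits (4.47%) lay more than 10 kb from any start site. The promoter share among the 3845 strongest peaks of each replicate was 57.0% ± 3.32 (SD, n = 3), and the coding share was 2.25% ± 2.19 (SD, n = 3), with 4.66% in replicate 2 and 0.364% in replicate 1.

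**Figure D1:**
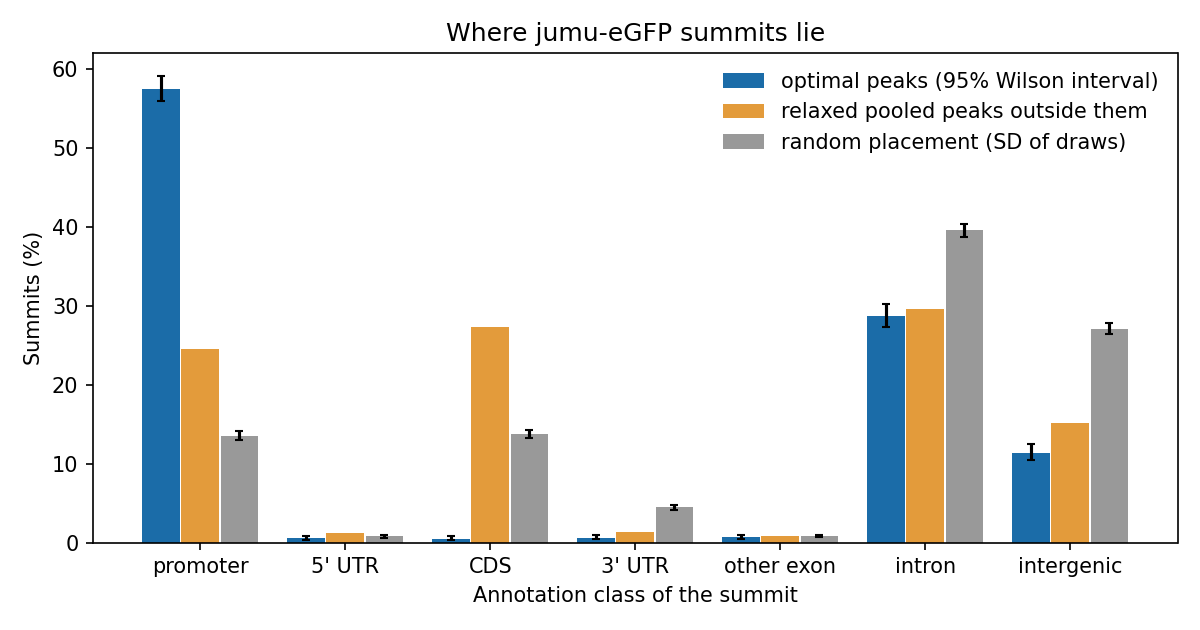
Share of summits (y axis, %) in each annotation class (x axis) for optimal peaks with 95% Wilson intervals, for relaxed pooled peaks that overlap none of them, and for random placements with the SD over draws. Promoters held 57.5% of optimal summits against 13.5% of random ones, and coding sequence held 0.494% against 13.8%.

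The 20 strongest peaks comprised 12 promoter, 6 intronic and 2 intergenic peaks. The strongest lay on 2L from 480827 to 481335 with a signal of 3722, in an intron of ush, a zinc finger cofactor of GATA factors, and 1371 bp from the start site of cbt. Its relative signal was 19.9 ± 0.889 (SD, n = 3). The next was at the promoter of Ugalt, a UDP-galactose transporter gene (X, 2703679 to 2704101, signal 3576, relative signal 19.0 ± 2.16, SD, n = 3). The promoter of CG14100 followed (3L, 19590417 to 19590811, signal 2969, relative signal 15.9 ± 1.41, SD, n = 3). The reference sequence of 31 bases around these 3 summits was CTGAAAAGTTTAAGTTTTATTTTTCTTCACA near cbt (2L, 481044 to 481074), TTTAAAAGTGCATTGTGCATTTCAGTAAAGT at Ugalt (X, 2703881 to 2703911) and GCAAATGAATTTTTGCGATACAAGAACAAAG at CG14100 (3L, 19590604 to 19590634).

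An internal promoter of the wing vein gene px carried a signal of 2639 (2R, 22514102 to 22514510). The Polycomb group gene ph-p had a promoter peak of 2327 (X, 2137147 to 2137561), and Chro, whose chromodomain protein binds interbands of polytene chromosomes, one of 2283 (3L, 22878697 to 22879097). Sox14, a transcription factor gene, had a promoter peak of 1897 (2R, 23978366 to 23978771), and Adf1, another, an intronic peak of 1861 (2R, 6662862 to 6663280). The kinase gene Lk6 had an intronic peak of 2169 (3R, 11760869 to 11761248). Promoter peaks with signals from 1705 to 2178 also lay at CG1888, PNPase, Art3, larp, CenG1A and mRpL41, and intronic peaks from 1806 to 2155 at CG11050, CG9663 and CG32772. The 2 intergenic peaks lay 11895 bp from CG13323 (2R, 13035127 to 13035553) and 915 bp from lncRNA:CR45643 (3R, 16222295 to 16222673).

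Because jumu modifies position-effect variegation, the spread over chromosome arms was compared, above all on the largely heterochromatic chromosome 4 and the X. Chromosome 4 held few peaks and the X slightly many. There were 14 peaks on chromosome 4, or 0.364% (0.217 to 0.610%), against 1.01% expected from its length, a ratio of 0.362 (exact binomial, adjusted p = 4.61e-05). The X held 760 peaks, 1.12 times the expectation (adjusted exact p = 0.00141), and 3L held 742, 0.919 times the expectation (adjusted exact p = 0.019). The binomial test treats peaks as independent draws, but peaks were clustered in some genes. Of the 5 genes with the most peaks, CG1677 (15), kirre (12), Raf (11) and CHES-1-like (10) lay on the X and ush (13) on 2L. These counts are not corrected for gene length. The 12 of kirre are about the number its length predicts at the X density of 32.3 peaks per Mb. How far clusters within genes made up the X excess was not tested. Arms 2L, 2R and 3R had ratios from 0.953 to 1.04 and did not pass. Among the 3845 strongest peaks of each replicate the chromosome 4 share was 0.338% ± 0.113 (SD, n = 3) and the X share 19.0% ± 0.600 (SD, n = 3). The X ratio of these peaks was 1.11 in replicate 1 (exact binomial p = 0.00198), 1.09 in replicate 2 (exact p = 0.0076) and 1.04 in replicate 3 (exact p = 0.204), while over the whole relaxed lists it was 0.973, 0.853 and 0.949. Against the relaxed pooled peaks, of which 0.319% lay on chromosome 4, the ratio turned to 1.14 (adjusted exact p = 0.705) and that of 3L was 0.928 (adjusted p = 0.0611), while the X ratio was 1.20 (adjusted p = 4.05e-07). Among the 1922 strongest optimal peaks the calls on the X (1.10) and 3L (0.917) ended (adjusted exact p = 0.0946 each). The call on 3L also ended without any one of the 3 replicates (0.930 to 0.938, adjusted exact p from 0.102 to 0.210). It ended too among the peaks that were also among the strongest of every replicate (adjusted exact p = 0.205). There the chromosome 4 ratio was 0.224, as it was without replicate 3. Without replicate 2 the 2L ratio of 1.10 passed (adjusted exact p = 0.0473). The sets without replicate 1, 2 or 3 held 2411, 2612 and 2655 peaks, so effects of the replicate and of fewer peaks were not separated. Against the share of start sites, a comparison chosen after seeing the data, 2R held fewer peaks (0.872, adjusted exact p = 0.000121) and 3L stood at 1.00 (adjusted p = 0.951).

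**Figure D2:**
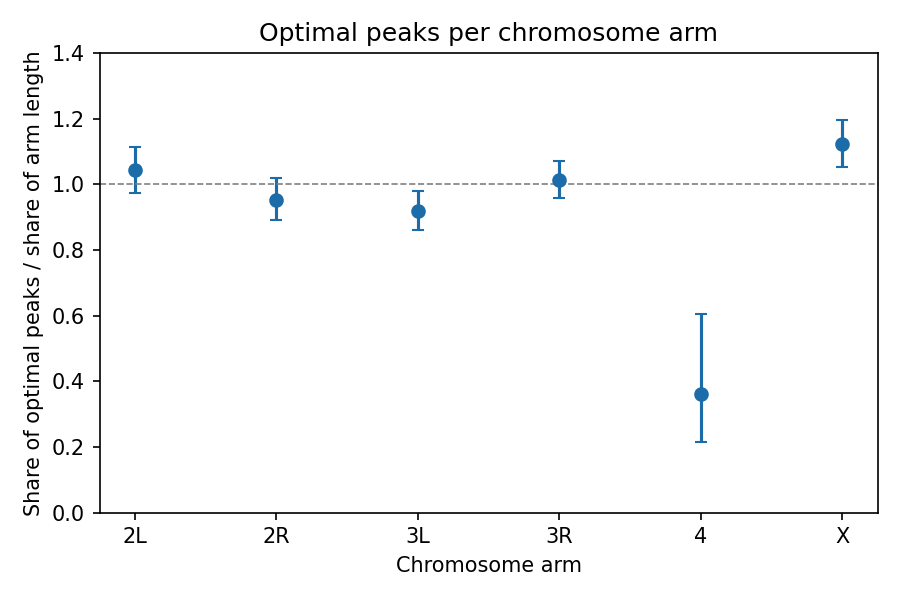
Share of the 3845 optimal peaks on each chromosome arm divided by the arm's share of summed length (y axis, no unit), with 95% Wilson intervals, by arm (x axis). Chromosome 4 lies at 0.362 and X at 1.12, and the dashed line marks a ratio of 1.

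The gene lists asked which kinds of genes had a peak at their promoters. Genes for ribosomal proteins, chromatin proteins and the cell cycle were bound more often than other genes, and genes for chemoreceptors, cuticle and seminal fluid proteins less often. In all, 3125 of 13945 protein-coding genes (22.4%) had an optimal summit within 1 kb of a start site, against 921 ± 30.9 (SD over 100 random placements). Of 31 lists, 4 were over-represented and 4 under-represented. Among ribosomal protein genes 49 of 85 were bound (57.6%, 47.0 to 67.6%, odds ratio 4.77, adjusted exact p = 6.47e-11). The strongest peaks lay at RpL34b (signal 732, relative signal 3.90 ± 0.519, SD, n = 3), RpL32 (690, 3.63 ± 0.824) and RpS20 (629, 3.32 ± 0.277). In 10 of the 49 genes, RpL32 and RpS20 among them, the strongest peak lay nearer to a start site of another gene.

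In the heterochromatin and position effect list 15 of 23 genes were bound (65.2%, 44.9 to 81.2%, odds ratio 6.52, adjusted exact p = 0.000103). They were led by Chro, the kinase gene JIL-1 (3L, 11092187 to 11092606, 5' UTR, signal 288) and the zinc finger gene pzg (3L, 21285810 to 21286229, signal 241). Apart from Chro, the 14 signals in this list ran from 116 to 288, with 117 at the gene for heterochromatin protein HP1a and 192 at Su(var)3-9, which encodes a histone methyltransferase. In 6 of the 15, pzg and the HP1a gene among them, another gene's start site was nearer. In the cell cycle and mitosis list 23 of 46 genes were bound (50%, 36.1 to 63.9%, odds ratio 3.48, adjusted exact p = 0.000279). Its strongest peaks lay at the mitotic kinase gene aurA (3R, 11962840 to 11963259, signal 382, with no summit of replicate 1 within 100 bp), the spindle checkpoint gene Bub3 (3R, 29675442 to 29675620, signal 377) and the replication licensing gene dup (2R, 15380607 to 15380740, signal 347). In 8 of the 23 another gene was nearer, as were Cap-D2 at Bub3 (108 bp against 122) and SRPK at dup (27 bp against 83). In the Polycomb and trithorax list 11 of 22 genes were bound (50%, 30.7 to 69.3%, odds ratio 3.47, adjusted exact p = 0.0159). After ph-p, the strongest were Trl, which encodes GAGA factor (3L, 14757105 to 14757311, signal 450), and Sfmbt (2L, 13176768 to 13176913, signal 362).

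None of 95 cuticle protein genes was bound, which allows a share of up to 3.16% (adjusted exact p = 9.32e-10), and none of 60 gustatory receptor genes, which allows up to 5% (adjusted p = 4.21e-06). Of 59 odorant receptor genes 2 were bound (odds ratio 0.121, 0.0143 to 0.458, adjusted exact p = 0.000561), Or88a with a signal of 186 and Or9a with 183. Both peaks lay nearer to other genes, CG12402 (414 bp against 710) and Neb-cGP (63 bp against 997). Of 44 genes with symbols of seminal fluid proteins 1 was bound, Sfp26Ad with a signal of 390 (odds ratio 0.0802, 0.00198 to 0.472, adjusted exact p = 0.00167), and that peak lay nearer to Gpdh1 (11 bp against 350). Without Acp1 and Acp65Aa, which encode cuticle proteins, it was 1 of 42 (0.0842, 0.00208 to 0.496, adjusted exact p = 0.00256). The lists of developmental genes did not pass against all other genes at 1 kb. They included segmentation (1 of 25, bcd, adjusted exact p = 0.0859), Notch signalling (9 of 20, adjusted p = 0.0859), Hox genes (0 of 8, which allows up to 37.5%), cardiac development (2 of 22, tin and Mef2), muscle development (4 of 23), neuroblasts and early CNS (4 of 27), glia (2 of 11), and hemocytes and lymph gland (4 of 23). The same held for trachea (1 of 13), gut and endoderm (3 of 14), germ line (2 of 13), Wnt signalling (6 of 23), Dpp signalling (3 of 14), and Toll and Imd immunity (5 of 21). It held as well for forkhead genes (3 of 17), ecdysone response (6 of 17), differentiated neurons (1 of 18), muscle structure (3 of 18), heat shock proteins (5 of 19), proteasome subunits (12 of 32), Jonah proteases (1 of 16) and the list for chorion and vitelline genes (1 of 16). The bound member of this last list was Cp190, which encodes a centrosomal and insulator protein. Without it and the centriolar gene Cp110 none of the 14 chorion and vitelline genes was bound, which allows up to 21.4% (adjusted exact p = 0.139). Segmentation genes passed as under-represented among genes with a relaxed peak (1 of 18, adjusted exact p = 0.0359) and within 5 kb (4 of 25, adjusted p = 0.0323). Within 5 kb Notch signalling (14 of 20, adjusted exact p = 0.0262), ecdysone response (13 of 17, adjusted p = 0.0143) and proteasome genes (22 of 32, adjusted p = 0.00731) also passed as over-represented, and chorion and vitelline genes, without Cp110 and Cp190, as under-represented (0 of 14, adjusted p = 0.0063).

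Against genes with a relaxed peak 4 of the 8 calls ended, those on cell cycle (odds ratio 2.01, adjusted exact p = 0.133), Polycomb (2.02, adjusted p = 0.357), odorant receptor (0.261, 0.0288 to 1.14, adjusted p = 0.259) and seminal fluid protein genes (0.229, 0.00515 to 1.71, adjusted p = 0.357), and the odds ratio was 2.59 for ribosomal protein and 3.44 for heterochromatin genes. The call on the heterochromatin list ended without replicate 1 (odds ratio 1.96, adjusted exact p = 0.419) and without replicate 3 (1.79, adjusted exact p = 0.605). Its odds ratio was 3.25 without replicate 2. The call on the Polycomb list ended without replicate 3 (2.90, adjusted exact p = 0.0869). These sets held only 2411 to 2655 peaks, so effects of the replicate and of fewer peaks were not separated. Without replicate 1 the odds ratios were 3.05 for ribosomal protein, 0.194 (0.0229 to 0.733) for odorant receptor and 0.128 (0.00318 to 0.755) for seminal fluid protein genes. Among peaks that were also among the strongest of every replicate 3 of the 8 calls held, those on ribosomal protein (odds ratio 3.16), cuticle protein and gustatory receptor genes. There the calls ended on Polycomb (3.46, adjusted exact p = 0.0635), cell cycle (2.39, adjusted p = 0.0662), odorant receptor (0.211, 0.0249 to 0.799, adjusted p = 0.0701), seminal fluid protein (0.140, 0.00346 to 0.823, adjusted p = 0.0719) and heterochromatin genes (1.68, adjusted p = 0.748). Among the 1922 strongest peaks the calls ended on heterochromatin (1.91, adjusted exact p = 0.629), odorant receptor (0.240, 0.0284 to 0.910, adjusted p = 0.150) and seminal fluid protein genes (0.159, 0.00394 to 0.937, adjusted p = 0.168). Within 5 kb, where 5601 genes were bound, the odds ratio was 3.41 for heterochromatin, 0.371 for gustatory receptor, 0.281 for seminal fluid protein and 0.174 for cuticle protein genes, and within 500 bp no odorant receptor gene was bound.

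**Figure D3:**
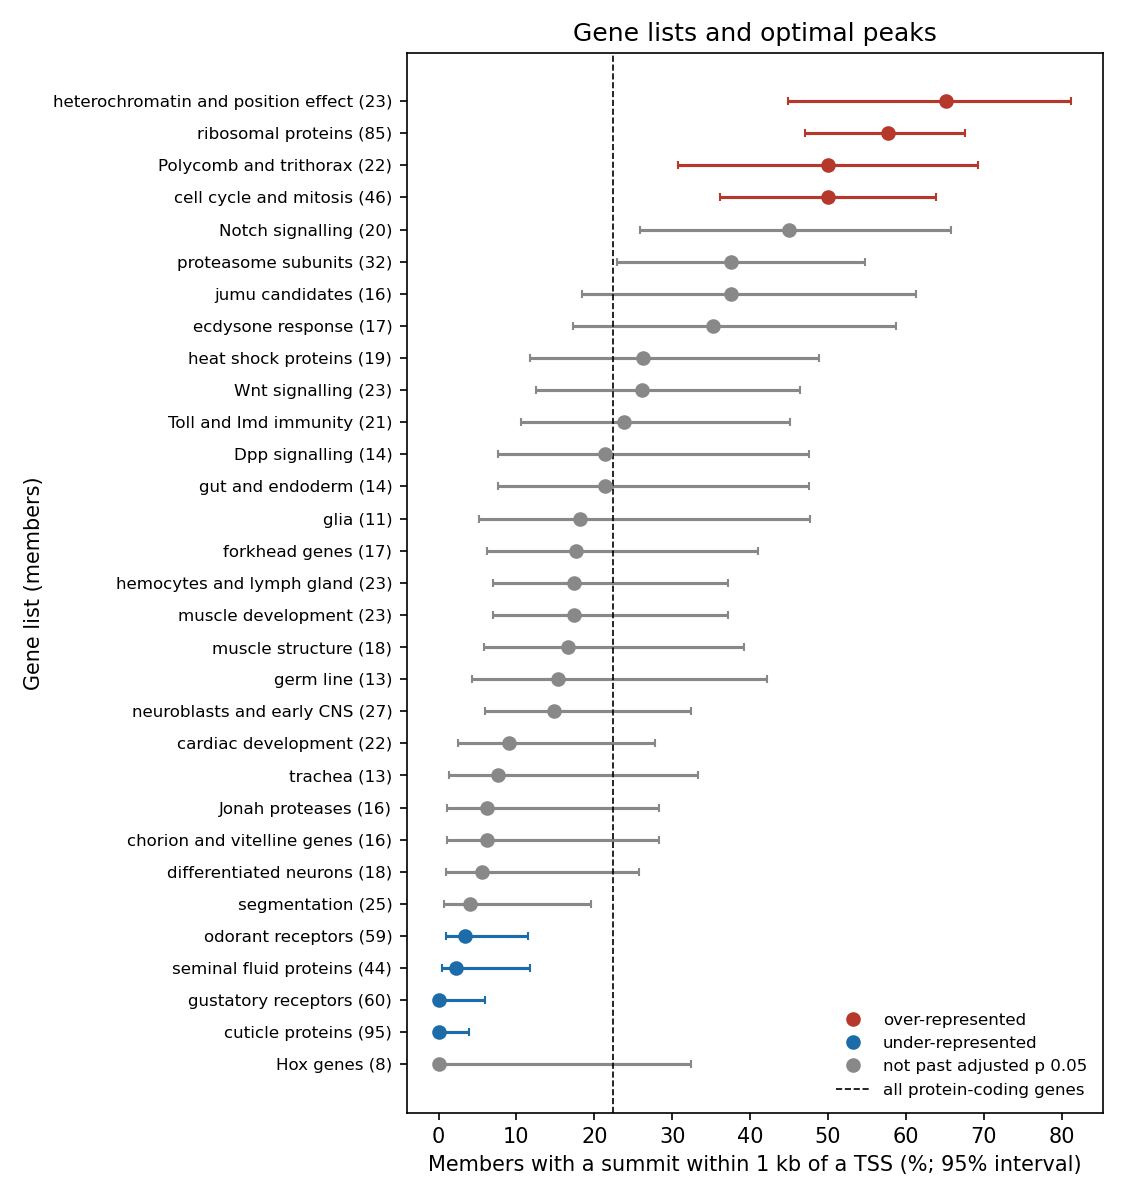
Share of the members of each gene list (y axis, number of members in brackets) with an optimal summit within 1 kb of a start site (x axis, %), with 95% Wilson intervals. The dashed line marks all protein-coding genes at 22.4%, and the lists past the threshold range from 0 for cuticle protein genes to 65.2% for heterochromatin genes.

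The candidate list held jumu and genes chosen for links to its known roles, 16 in all. Of these, 6 had a summit within 1 kb of a start site (37.5%, 18.5 to 61.4%), which did not differ from other genes past the threshold (odds ratio 2.08, adjusted exact p = 0.409). They were cact, an inhibitor of Toll signalling (signal 551), CHES-1-like, the other forkhead gene of the jumu family (451), the mitotic kinase gene polo (314), the cardiac homeobox gene tin (119), the HP1a gene (117) and numb, a Notch inhibitor (115.3). The peak at polo (3L, 20309800 to 20310219) had a relative signal of 1.72 ± 0.471 (SD, n = 3), and that at tin (3R, 21378552 to 21378971) 0.629 ± 0.182 (SD, n = 3). The peaks near numb and the HP1a gene were not matched in all 3 replicates, and the latter summit lay nearer to Ssb-c31a, at 58 bp.

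Counting peaks in the gene or within 1 kb of it, 11 of the 16 candidates had one. The share among all genes was not computed, and longer genes catch more peaks, so this count shows no enrichment. The jumu gene itself carried 2 intronic peaks, from 10351304 to 10351723 on 3R (signal 222, relative signal 1.18 ± 0.277, SD, n = 3) and from 10356877 to 10357296 (signal 298, relative signal 1.55 ± 0.406, SD, n = 3). The Wnt receptor gene fz had 3 intronic peaks, the strongest from 14303935 to 14304187 on 3L with a signal of 719, and fz2 had 2 in introns and 1 just outside the gene, with signals from 112 to 152. Both are long genes, and at the 3L density of 26.4 peaks per Mb their peak counts are close to what their lengths predict. Myc had 2 intronic peaks, and Dif had 2 peaks beside the start site of lncRNA:CR44409. No optimal peak was counted for bin, dl, Col4a1, NimC1 or esg.

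Some genes held many peaks. CG1677 on the X had 15 optimal peaks within the gene or 1 kb of it, ush 13, the myoblast fusion gene kirre 12, the kinase gene Raf 11 and CHES-1-like 10. In CHES-1-like 8 of the 10 were intronic, with signals from 129 to 563. None of the 12 peaks of kirre lay within 1 kb of one of its start sites, while Raf had a peak in its 5' UTR (X, 2296149 to 2296372, signal 647, relative signal 3.52 ± 0.270, SD, n = 3). These counts are not corrected for gene length, and kirre spans X from 2740384 to 3134532. The X as a whole held 32.3 optimal peaks per Mb. The 12 peaks of kirre are therefore about the number its length predicts and are not a cluster.

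The consensus words asked which sequences lay under the summits. The DRE and Motif1, words known from housekeeping promoters, were far more frequent there than in the flanks, at promoter peaks, and the forkhead word only a little. The flanks were centred 500 bp away, so those of promoter summits lay mostly outside the region next to the start site. Promoters without a peak were not used as a control. The folds of the DRE and Motif1 therefore do not tell a trait of these peaks from a trait of promoters. The DRE (DNA replication-related element) TATCGATA was found in 119 of 3845 summit windows (3.09%, 2.59 to 3.69%) and 16 flanking windows, a 7.44-fold difference (adjusted exact p = 8.54e-20). Core promoter Motif1, YGGTCACACTR, was found in 33 and 3 windows (11-fold, 3.45 to 56.1, adjusted exact p = 5.30e-07). The word KTTTAAA was found in 510 and 237 (2.15-fold, adjusted exact p = 2.28e-24). It is called Motif6 here as a label only and is not taken to be a core promoter element. The TATA word STATAWAAR was 2.08-fold higher (adjusted exact p = 0.000423). The forkhead word RYAAAYA was found in 28.0% (26.6 to 29.5%) of summit windows and 23.4% of flanks (1.20-fold, adjusted exact p = 5.25e-06). The forkhead-like word GACGC, known from FOXN proteins, was lower at summits (6.58% and 12%, adjusted exact p = 4.47e-16).

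Also lower at summits were CAGGAC (0.233-fold, adjusted exact p = 2.61e-12), CACACACA (0.352-fold, adjusted p = 3.47e-11), the GAGA word (0.520-fold, adjusted p = 0.000128) and the Zelda word CAGGTAR (0.607-fold, adjusted p = 0.0276). The E-box, GATA, initiator and Hox words did not pass (adjusted p from 0.106 to 0.402). Against relaxed summits, however, the E-box word was lower (0.651-fold, adjusted exact p = 4.55e-07). The GATA (1.55-fold, adjusted exact p = 0.00485) and Hox words (1.78-fold, adjusted exact p = 1.60e-15) were higher. Relaxed summits lay in coding sequence in 27.3% of cases, against 0.494% of optimal summits, and were not matched for class or base composition. The Hox word also passed as higher without any one replicate (1.28 to 1.43-fold, adjusted exact p from 0.00340 to 0.0365), among the 1922 strongest peaks (1.33-fold, adjusted p = 0.0325) and within 100 bp of the summit (1.19-fold, adjusted p = 0.00643). Among peaks away from promoters the E-box word was lower (0.540-fold, adjusted exact p = 0.00826) and the GATA word higher (2.31-fold, adjusted p = 0.0240). The DRE was found in 5.20% of promoter summits and 0.245% of other summits (Fisher's exact test, odds ratio 22.4, adjusted p = 3.42e-22), and Motif1 in 1.36% and 0.184% (odds ratio 7.48, adjusted p = 0.000232). At summits away from promoters neither differed from the flanks past the threshold, with the DRE in 0.245% of both windows and Motif1 in 3 summit and 2 flanking windows (adjusted exact p = 1 each). The E-box word (4.66% and 2.08%, odds ratio 2.30, adjusted exact p = 9.68e-05) and GACGC (7.60% and 5.20%, odds ratio 1.5, adjusted p = 0.0106) were also more frequent at promoter summits. Motif6 was found in 13.6% of promoter and 12.8% of other summits (adjusted exact p = 0.599) and the forkhead word in 26.9% and 29.6% (adjusted p = 0.205), which did not pass. Relaxed summits lay at promoters, where the DRE and Motif1 were concentrated, in 24.5% of cases, against 57.5% of optimal summits. They were not matched for this, so a fold against them mixes word and location. With relaxed summits as the control the fold was 4.61 for the DRE, 2.64 for Motif1, 0.636 for CACACACA and 0.145 for CAGGAC. It was 4.71 for Motif1 against flanks at 1000 bp, and 0.569 for CACACACA and 0.788 for GAGA within 100 bp of the summit. Without replicate 2 it was 17.8 for the DRE. Motif1, with 1 flanking window, stood at 17 (2.66 to 710) without replicate 1 and 21 (3.38 to 868) without replicate 2. The sets with 1 replicate left out held 2411 to 2655 peaks, so for every word effects of the replicate and of fewer peaks were not separated. The call on TATA ended without replicate 3 (1.5-fold, adjusted exact p = 0.118), and that on GAGA with relaxed summits as the control (0.862-fold, adjusted p = 0.355) or flanks at 1000 bp (0.707-fold, adjusted p = 0.0853). The call on Zelda ended without replicate 1 (0.60-fold, adjusted exact p = 0.0699) or 3 (0.643-fold, adjusted p = 0.118), within 25 bp of the summit (0.60-fold, adjusted p = 0.142), among the 1922 strongest peaks (0.92-fold, adjusted p = 0.954) and among the peaks also strongest in every replicate (0.815-fold, adjusted p = 0.560). GC content was 37.8% ± 9.26 (SD over peaks) in summit windows and 43.9% ± 7.74 at 500 bp.

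**Figure D4:**
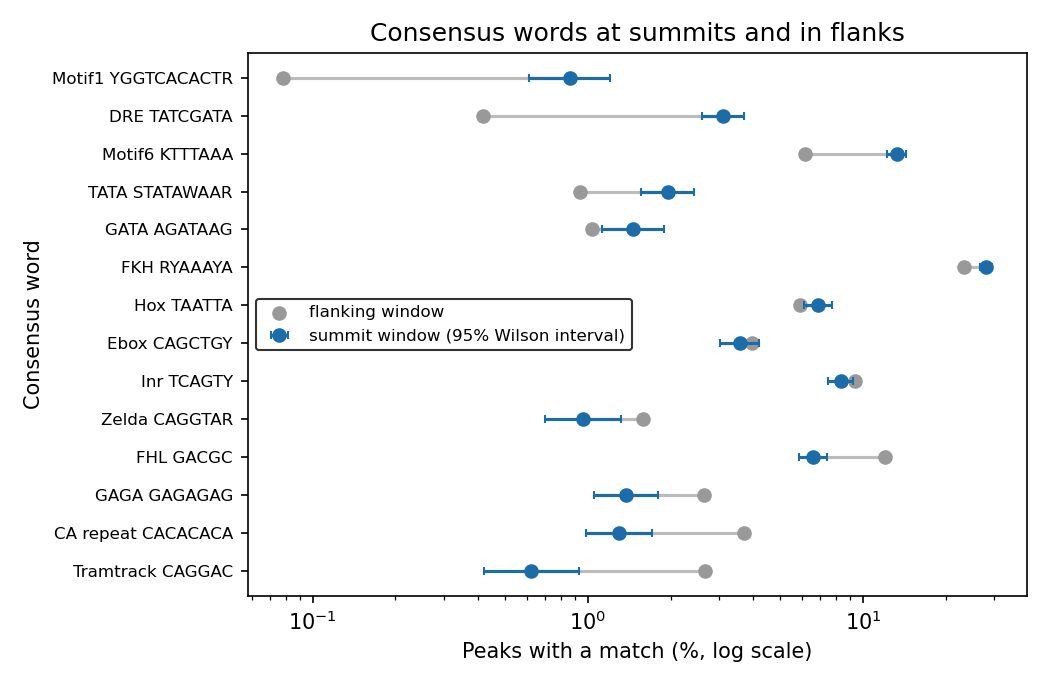
Share of the 3845 optimal peaks with a match to each consensus word (y axis) in the summit window (95% Wilson interval) and in the flanking window (x axis, %, log scale). DRE and Motif1 differ most, by 7.44-fold and 11-fold, and the forkhead word by 1.20-fold.

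Promoter peaks were slightly stronger than other peaks. The median signal was 186.9 (quartiles 141.4 and 287.1) at 2211 promoters and 173.6 (134.0 and 263.9) at 1634 other places, a difference of 13.3 (permutation p = 0.00101). Within each replicate the ratio of the medians was 1.06, 1.10 and 1.12, with promoters higher in 3 of 3. Without replicate 2 the difference was 10.8 (permutation p = 0.0956), without replicate 3 it was 20.5, and among the 1922 strongest optimal peaks 6.96 (permutation p = 0.269). The sets without replicate 2 and 3 held 2612 and 2655 peaks, so effects of the replicate and of fewer peaks were not separated.

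The same experiment processed against the older build dm3 gave 3738 optimal peaks, 107 fewer than in dm6. Chromosome 4 had 14 in both builds, the X 738 against 760 and 3R 904 against 933. No signal value was shared exactly between the lists, so single peaks were not paired across builds.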

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

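The relaxed lists of the older build dm3 held peaks on heterochromatic and unplaced contigs outside the 6 arms, which none of the comparisons used and for which no control sample was analysed here. They were counted after the lists had been seen. Each count was above the 3 that a count of 0 allows, which says little for relaxed lists that include background by design. The pooled list had 41 such peaks. Replicate 1 had 54, replicate 2 had 194 and replicate 3 had 63, each of 30000. The optimal dm3 list had none, and no explanation was tested.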

How the results depend on the processing

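Arms against the share of start sites, the dm3 count of optimal peaks and the gene lists without members of another kind were chosen after seeing the data. The promoter share stayed above random placement under every alternative run (48.2 to 66.9%). Peaks matched in all replicates moved to 61.7% at 50 bp, 96.8% at 200 bp and 94.9% by interval overlap, and to 90.3 to 93.7% with one replicate left out. The rank correlation between replicates moved to 0.799 at 50 bp and 0.811 as Pearson's r of log2 signal, with 0.701 to 0.779 when one replicate was left out. Top-list overlap moved to 54.0% at 50 bp, 72.8% at 200 bp and 75.5% with the shorter top lists, with 63.1 to 69.7% when one replicate was left out. Wider matching and fewer replicates to match raise a matched share by construction. The number of arms called fell from 3 to 1 among the 1922 strongest peaks and to 1 against relaxed peaks. There the chromosome 4 ratio turned to 1.14, and against start sites the 3L ratio turned to 1.00. Gene lists called were 8 as planned, 3 for peaks among the strongest of every replicate, 5 for the 1922 strongest, 13 with a 5 kb window (these 8 and 5 more), 8 and 13 without members of another kind, and 5 against genes with a relaxed peak (4 of the 8 and segmentation), with 6 to 8 when one replicate was left out. Bound genes numbered 1982, 1772 and 5601 in the first 3 of these settings. They numbered 2133 to 2307 when one replicate was left out, in sets of 2411 to 2655 peaks. Fewer peaks or a wider window give fewer or more genes. Words called numbered 9 to 12. The promoter difference was 6.96 among the 1922 strongest peaks and 10.8 to 20.5 when one replicate was left out. Apart from these constructions, the cause was not tested. Of the alternative values 202 were labelled as keeping direction and call or as not moving, 32 kept direction but lost the call, 22 moved and 2 reversed. The first label was broad for counts. It took in a fall from 3125 to 2133 bound genes without replicate 1, and from 8 to 6 gene lists called without replicate 3. Motif1 gave no fold without replicate 3, among the 1922 strongest peaks or within 25 bp of the summit, where no flanking window held it, and its call stayed. The set of peaks that were also among the strongest of every replicate held 2213 peaks. Depth is unknown, so weak peaks carry no stated error. Arms in dm3 against dm3 lengths were not run, and no paired analysis was possible because the series has 1 group.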

Other observations

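The tests of chromosome 4 against start sites, by replicate and within each replicate, those of Motif6 and TATA against words with the same letters, and that of summit words across arms, were chosen after the result was seen, and the planned comparison of arms with relaxed peaks was only then taken as a test of low detection. Several classes of genes that make no protein were bound less often than the 22.4% of protein-coding genes. An optimal summit lay within 1 kb of 304 of 3261 genes annotated as non-coding RNA (9.32%, 8.37 to 10.4%, Fisher's exact p = 1.40e-72) and of 41 of 269 snoRNA genes (15.2%, 11.4 to 20%, Fisher's exact p = 0.0048). Of 32 snRNA genes 7 were bound (21.9%, Fisher's exact p = 1). Some members of lists that did not pass had strong peaks within 1 kb of a start site, chosen here after their values were seen. They included the small heat shock protein gene Hsp27 (signal 661), the neuronal RNA-binding protein gene elav (638), the transporter gene E23 (510), the forkhead gene fkh (485) and the ecdysone response gene Eip75B (365, with 7 optimal peaks in the gene or within 1 kb).

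The share of summits with the DRE was 1.56% among the 961 strongest peaks (15 peaks, 0.948 to 2.56%), 3.33% among the next 961 (2.37 to 4.66%), 4.47% among the 961 after those (3.34 to 5.97%) and 3.01% among the 962 weakest (2.11 to 4.30%). These differences were not tested. The forkhead word was found in 25.8 to 29.3% of summits in each of these 4 groups. Replicate 2 stood apart in its relaxed list, with 47 of 30000 peaks on chromosome 4 against 179 and 208 in replicates 1 and 3.

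The forkhead word was 1.20-fold more frequent at summits, and the forkhead-like word GACGC 0.546-fold, both consistent with the AT-rich composition of summits. Among 104 other words with the letters of RYAAAYA the median fold was 1.28, and the forkhead word stood at percentile 18.3. The word GACGC stood at percentile 20.7 among 29 words with its letters, and TATA at percentile 89.5 among 200. Composition accounts for neither the DRE nor Motif6, each at percentile 100, among 199 and 139 words. Motif1, CAGGAC, CACACACA and the GAGA, Zelda, E-box, GATA and Hox words were not compared in this way, so composition stays open for them. Among peaks away from promoters the forkhead word was 1.11-fold higher (exact McNemar p = 0.0544); the criterion written beforehand counted this as pointing to promoter sequence, but after the value was seen it was read as leaving the question open, since a missed threshold shows no absence, and no biological explanation was tested.

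Ribosomal protein promoters were over-represented, with an odds ratio of 4.77 against all other protein-coding genes. Being listed at all did not account for all of this, since among genes with a relaxed peak the odds ratio was 2.59 (adjusted exact p = 0.000261). Nor did crowding of genes and the number of start sites, with a Mantel-Haenszel odds ratio of 3.17 (1.99 to 5.06). Both values were below 4.77, so each may account for a part, and they were not tested together. Heavy transcription of any kind was argued against by tRNA genes, of which 6.90% (4.51 to 10.4%) were bound, fewer than protein-coding genes (Fisher's exact p = 2.65e-12). That covers tRNA genes, made by another polymerase and often in near-identical copies, so signal that follows heavy transcription by RNA polymerase II or open promoters was not tested and no biological explanation was either.

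Chromosome 4 held 0.362 times the peaks its length predicts. Fewer start sites did not account for all of the deficit, with a ratio of 0.469 to their share (adjusted exact p = 0.00451). A loss in replicate 2 alone did not account for it, since the strongest peaks of replicates 1 and 3 reached at most 0.413. The relaxed pooled list was also sparse there, with a ratio of 1.14 (adjusted exact p = 0.705), so the deficit may in part reflect low detection of any peak on chromosome 4. Within replicates this stays open, since the odds ratio of lying on chromosome 4, strongest against weaker peaks, was 0.621 in replicate 1, 1.4 in replicate 2 and 0.565 in replicate 3 (Fisher's exact test, adjusted p from 0.0842 to 0.381), with whole-list ratios to length of 0.593, 0.156 and 0.689. No biological explanation was tested.

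A further hypothesis was that summit words recur across the genome. Of the 10 words of 8 bases most over-represented at summits on 2L, 3L and X, 8 were also more frequent on 2R, 3R and 4, beyond the 95th percentile of words with the same letters. AGTGCTGC (2.36-fold against 3) and CTTTTAAA (2.125-fold against 3.33) stayed below that percentile. The 8 that passed are not separate sequences. ATCGATAG, TATCGATA, ACTATCGA and GCTATCGA overlap the DRE, and CAACACTG, CAGCACTG and CACTGTGC share the bases CACTG. Besides DRE-like words such as ATCGATAG (53 summit and 5 flanking windows of 1639, exact McNemar adjusted p = 3.50e-10), they included CAACACTG (37 and 6, adjusted p = 4.09e-06) and CAGCACTG (30 and 6, adjusted p = 0.000139), which were not among the planned words. No explanation was tested. All optimal peaks had been searched for words before the arms were split, so the second set of arms is not independent evidence, and the words with the same letters were redrawn at random after a first, alphabetical choice.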
